A study of Danio rerio with 12 samples.

How the data were processed

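Livers were dissected from adult wild-type zebrafish (Danio rerio) that had been exposed each day to β-estradiol or to DMSO, the solvent control, for 6 weeks from 3 months after fertilization, with the fish kept in single tanks to control feeding, per the labels' protocols. RNA was extracted with Trizol, treated with DNase and made into stranded sequencing libraries with a NEBNext Directional kit, per the labels' protocols. The 12 libraries fall into 4 groups of 3: male DMSO, male estradiol, female DMSO and female estradiol. The labels do not state that each library came from a separate fish, so the p-values measure the spread between these libraries. The libraries carry numbers from 7 to 12 in the DMSO groups and from 19 to 24 in the estradiol groups, so any difference between library runs cannot be told apart from the treatment.

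The authors trimmed reads with cutadapt, aligned them with TopHat2 2.0.11 and estimated expression with Cufflinks 2.2.1 on the danRer7 build, per the submitters' processing notes. The gene annotation is not given there. The deposited table holds 1 FPKM value (fragments scaled to transcript length and to the mapped fragments of the library) per gene symbol and library. This unit was inferred from the values and from Cufflinks, because the header names none. Sums of FPKM differ between libraries, so the values are not on a common total, and it is not stated whether a further scaling between libraries was applied. Whole fragment counts could not be recovered from the table: at most 0.948% of 1055 genes with low values fell in one bin 0.01 wide on the log2 scale. The depth of the libraries is therefore unknown, and no counting interval or detection limit is given. No genome sequence was used here, so genes are named by the symbols of the table without coordinates. Of its 14581 genes, 11801 carry a current symbol of the RefSeq gene table and 14211 a symbol or synonym of it.

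Genes with at least 1 FPKM in at least 3 of the 12 libraries were tested, which left 9190. Values were transformed as log2(FPKM + 1). A linear model with 4 group means was fitted to all 12 libraries with limma 3.58.1 in R 4.3.3 (lmFit, contrasts.fit, eBayes with an intensity trend), and p-values were adjusted by the Benjamini-Hochberg method with a threshold of 0.05. There were 5 contrasts: estradiol against DMSO in males, the same in females, females against males under DMSO, females against males under estradiol, and the interaction, which is the effect of estradiol in females minus that in males. "Rose" and "higher" mean past this threshold in favour of the first-named group. Tables and figures were made with Python 3.11.15, pandas 2.3.3, numpy 2.4.6, scipy 1.17.1 and matplotlib 3.10.9. The fit was tested on simulated data for the estradiol effect in males, with 9190 genes and 5 runs. It recovered 4.4% of genes changed by 1 on the log2 scale, 54.0% of those changed by 2, 76.0% by 3 and 90.8% by 4, and 4.25% of its calls were false. The simulated noise was independent between genes and of equal size in all libraries, so these rates need not hold for the real libraries.

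A set of 46 genes is listed at exactly 0 in every library of at least 1 group and at 1 FPKM or more in every library of another. They include the vitellogenins. Because an exact 0 can also be a failed estimate, their values are given without folds and the vitellogenin list without a test, and each comparison was also run without them. The other list tests keep those among their members, which are 3 apolipoprotein and plasma protein genes, 2 genes of the ovary list and 1 of fatty acid and triglyceride synthesis.

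Genes were named by a rule written before the data were examined. For each pairwise comparison it took the 10 largest rises and the 10 largest falls among genes past the threshold with a mean of at least 5 FPKM in the higher group and no overlap between the 2 groups, leaving clone names unnamed. For the interaction it took the 10 smallest adjusted p. It added up to 4 members with the smallest p from each gene list with a member past the threshold, and every tested member of the lists of receptors and vitellogenins. Some of these genes are left out of the text for length. The 35 gene lists, also written before the data were examined, cover estrogen receptors with other nuclear receptors (esrra, ar, pgr and nr0b2a among the genes tested), vitellogenins, other estrogen-responsive liver genes, protein folding and the unfolded protein response, the secretory pathway, PI3K/AKT/mTOR components, ribosomal proteins, ribosome biogenesis, translation factors, cell cycle, cholesterol synthesis, fatty acid synthesis, fatty acid oxidation, glycolysis and gluconeogenesis, bile acids, xenobiotic metabolism, coagulation, complement, apolipoproteins and plasma proteins, the growth hormone axis, oxidative phosphorylation, the proteasome, heat shock, the circadian clock, and markers of stellate, biliary, endothelial, leukocyte and red blood cells, exocrine pancreas, intestine, muscle, ovary and testis. 1 more of the 35 is not reported here, though it was tested with the others and is included in the adjustment and in counts of lists.

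Each list was tested with limma's camera at a preset correlation between genes of 0.01, adjusted over the lists. Camera was repeated with a correlation estimated from the residuals, and limma's fry was run beside it. Fry asks whether the genes of a list move, on balance, one way, and does not compare them with other genes. The alternatives were a pseudocount of 0.1, no filter and a filter of 5 FPKM, quantile normalization, median-of-ratios scaling, rescaling without the vitellogenins and the 10 highest genes, the replicate number as a block, only the groups compared, no intensity trend, array weights, and each of the 12 libraries left out in turn. Chosen after the data were seen were the run without the genes listed at 0, the level of the ovary list as a covariate, the run without 4 estradiol libraries in which the ovary list had a mean log2 level above 4, and the run without 2 female DMSO libraries in which the intestine list did.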

Results

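Liver RNA was sequenced from adult wild-type zebrafish in 12 libraries, 3 in each of 4 groups: males and females given DMSO, and males and females given β-estradiol, the main ovarian estrogen, for 6 weeks. The title of the study names GPER1 (a membrane-bound estrogen receptor), PI3K/mTOR signalling and the sex difference in liver growth and cancer, so the comparisons ask what estradiol changed in each sex and whether it moved male livers toward the female state. The sum of FPKM per library ran from 660052 to 731829 in male DMSO, 304905 to 786203 in male estradiol, 791666 to 906620 in female DMSO and 485549 to 1217095 in female estradiol. The Spearman correlation across genes between libraries of the same group was 0.945 to 0.955 in male DMSO, 0.775 to 0.929 in male estradiol, 0.910 to 0.938 in female DMSO and 0.790 to 0.905 in female estradiol. The transcript of the receptor named in the title, gper1, was near the floor, with 0 to 0.0490 FPKM over the 12 libraries, and was not among the genes tested.

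Transcripts of other organs differed between libraries and moved with the groups. Oocyte genes, such as those for the egg coat protein zp3b, had a mean log2 level of 6.40, 1.83 and 5.43 in male estradiol replicates 1 to 3 and of 6.48, 0.38 and 4.50 in female estradiol. In DMSO it was 0.30 to 0.51 in males and 0.93 to 3.35 in females. zp3b itself reached 609 and 286 FPKM in male estradiol replicates 1 and 3 and at most 0.294 in male DMSO. Digestive enzyme genes of the exocrine pancreas had mean log2 levels of 6.81 to 7.20 in male DMSO and 5.85 to 8.16 in female DMSO, against 2.503 to 4.30 in male estradiol and 1.29 to 4.10 in female estradiol. Intestine genes stood at 5.90 and 5.30 in female DMSO replicates 1 and 2 and at 0.34 to 2.65 in the other 10 libraries. Of the 26 oocyte and germ cell genes, 1 had at least 1 FPKM in every male DMSO library, and 1, ccnb1, was also in the cell cycle list.

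**Figure D1:**
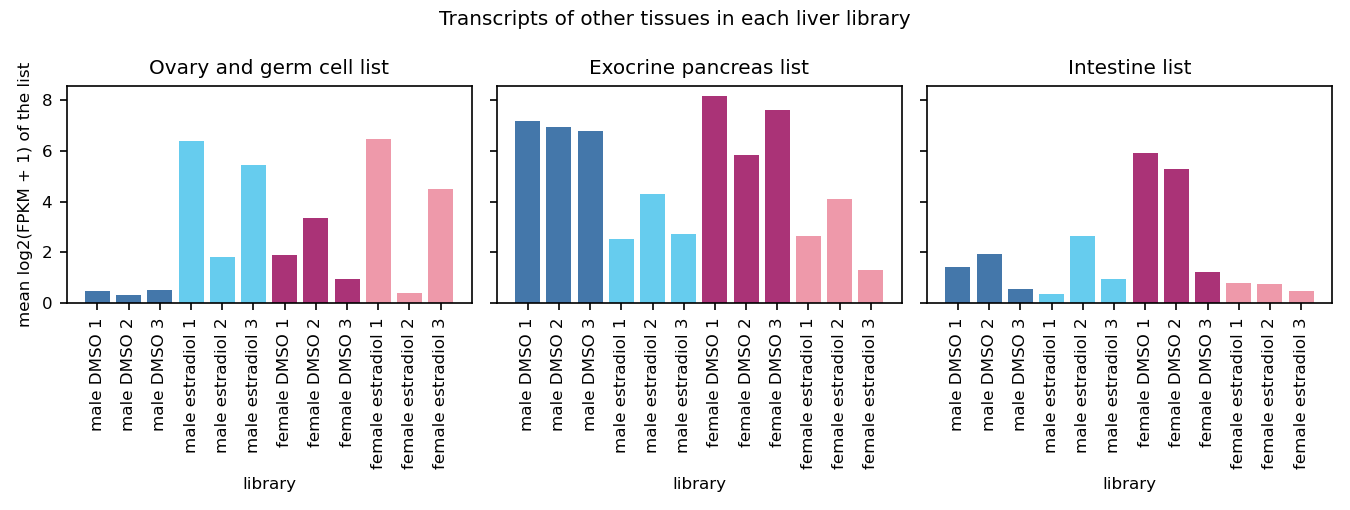
Mean log2(FPKM + 1) of the ovary, exocrine pancreas and intestine lists (vertical axis) in each of the 12 libraries, 1 bar per library, by group. The ovary list lies above 4 in 4 estradiol libraries, 2 of each sex, and the intestine list above 4 in 2 female DMSO libraries.

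Some of the most abundant liver genes were listed at exactly 0 in whole groups. The apolipoprotein genes apoa1b and apoa2 and the gene pmepa1 were at 0 in all 3 male DMSO libraries, while pmepa1 ran from 7338 to 45609 FPKM elsewhere. tfa, the gene for the iron carrier transferrin, was at 0 in all 6 DMSO libraries and ran from 2076 to 16527 FPKM in the estradiol libraries. The vitellogenins, egg yolk precursors that liver makes under estrogen, were listed in the opposite pattern: vtg1, vtg2, vtg4, vtg5, vtg6 and vtg7 were at 0 in all 9 female and estradiol libraries, and vtg1 ran from 35.0 to 310.3 FPKM in male DMSO. An exact 0 cannot be told from a failed estimate here, so no fold is given for these 46 genes and the vitellogenin list has no usable test.

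In males, estradiol raised nots and esr1 and lowered cyp2k22, hsd17b3, elovl6, me1 and g0s2. Lower with them were 19 of 23 genes of the exocrine pancreas. Their transcripts belong to another organ, so a fall in liver cannot be told from a difference in pancreas tissue between the samples. nots, the gene for nothepsin, an aspartic protease known from the liver of female fish, rose from 6.23 ± 2.70 to 2631 ± 1656 FPKM (mean ± SD, n = 3; log2 change 8.26, SE 0.67, adjusted p = 4.21e-05). cyp2k22, a cytochrome P450 gene, fell from 776 ± 199 to 0.0896 ± 0.0337 FPKM (log2 change -9.44, SE 0.57, adjusted p = 2.45e-06). hsd17b3, whose enzyme makes testosterone, fell from 68.4 ± 42.6 to 0.199 ± 0.137 FPKM (log2 change -5.69, SE 0.39, adjusted p = 7.95e-06). Falling with them were elovl6, a fatty acid elongase (log2 change -5.58, SE 0.79, adjusted p = 0.00317), me1, the malic enzyme that supplies NADPH (-5.05, SE 0.56, adjusted p = 6.06e-04), and g0s2, an inhibitor of triglyceride lipase (-4.37, SE 0.66, adjusted p = 0.00402). The estrogen receptor gene esr1 rose from 1.07 ± 0.284 to 16.1 ± 17.7 FPKM (log2 change 2.54, SE 0.60, adjusted p = 0.0382).

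Other rises in males were rtn1a, which encodes a reticulon of the endoplasmic reticulum (log2 change 4.79, SE 0.72, adjusted p = 0.00402), and lipg, which encodes a secreted lipase (4.57, SE 0.53, adjusted p = 9.35e-04). Among the falls, apoa1a, the gene for an HDL apolipoprotein, went from 8717 ± 1286 to 216 ± 52.6 FPKM (log2 change -5.35, SE 0.47, adjusted p = 8.47e-05). rbp2a, a retinol-binding protein gene, fell from 2509 ± 225 to 122 ± 146 FPKM (-5.08, SE 0.81, adjusted p = 0.00482). Of 9190 genes tested with limma, 348 passed the threshold, of which 81 rose and 267 fell, and 2473 had an unadjusted p under 0.05 where 459.5 would by chance. Of all genes tested 30.0% had no overlap between the 3 estradiol and the 3 DMSO libraries, where chance gives 10%. Rescaling without the vitellogenins and the 10 highest genes gave 113 rises and 130 falls, with the median log2 change of all genes at 0.61 in place of 0.21 (-0.05 after quantile normalization, 0.06 after median-of-ratios scaling). The count was 104, 126 and 172 without male DMSO replicates 1, 2 and 3, 183 without male estradiol replicate 1, 2220 without male estradiol replicate 2 and 661 without female estradiol replicate 1. Of the 2220 genes 1449 rose and 771 fell, while falls outnumbered rises in every other run that left out 1 library. Rises also outnumbered falls with the ovary list level as a covariate (106 and 99) and with array weights (2971 and 2555), which did not converge. The same held without the 4 estradiol libraries rich in oocyte transcripts, so the excess of falls did not hold in every alternative. The number of genes past the threshold also depended on the fit and on which groups or libraries were kept. It was 220 in a fit of the male groups alone, 205 with the ovary list level as a covariate, 197 without the 2 female DMSO libraries rich in intestine transcripts and 693, with 223 of the 348 genes among them, without the 4 estradiol libraries rich in oocyte transcripts. The esr1 call ended without male DMSO replicate 1, 2 or 3 (adjusted p = 0.135, 0.130 and 0.119), male estradiol replicate 3 (0.0590), female DMSO replicate 1, 2 or 3 (0.0555, 0.0507 and 0.0570) or female estradiol replicate 3 (0.0555).

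**Figure D2:**
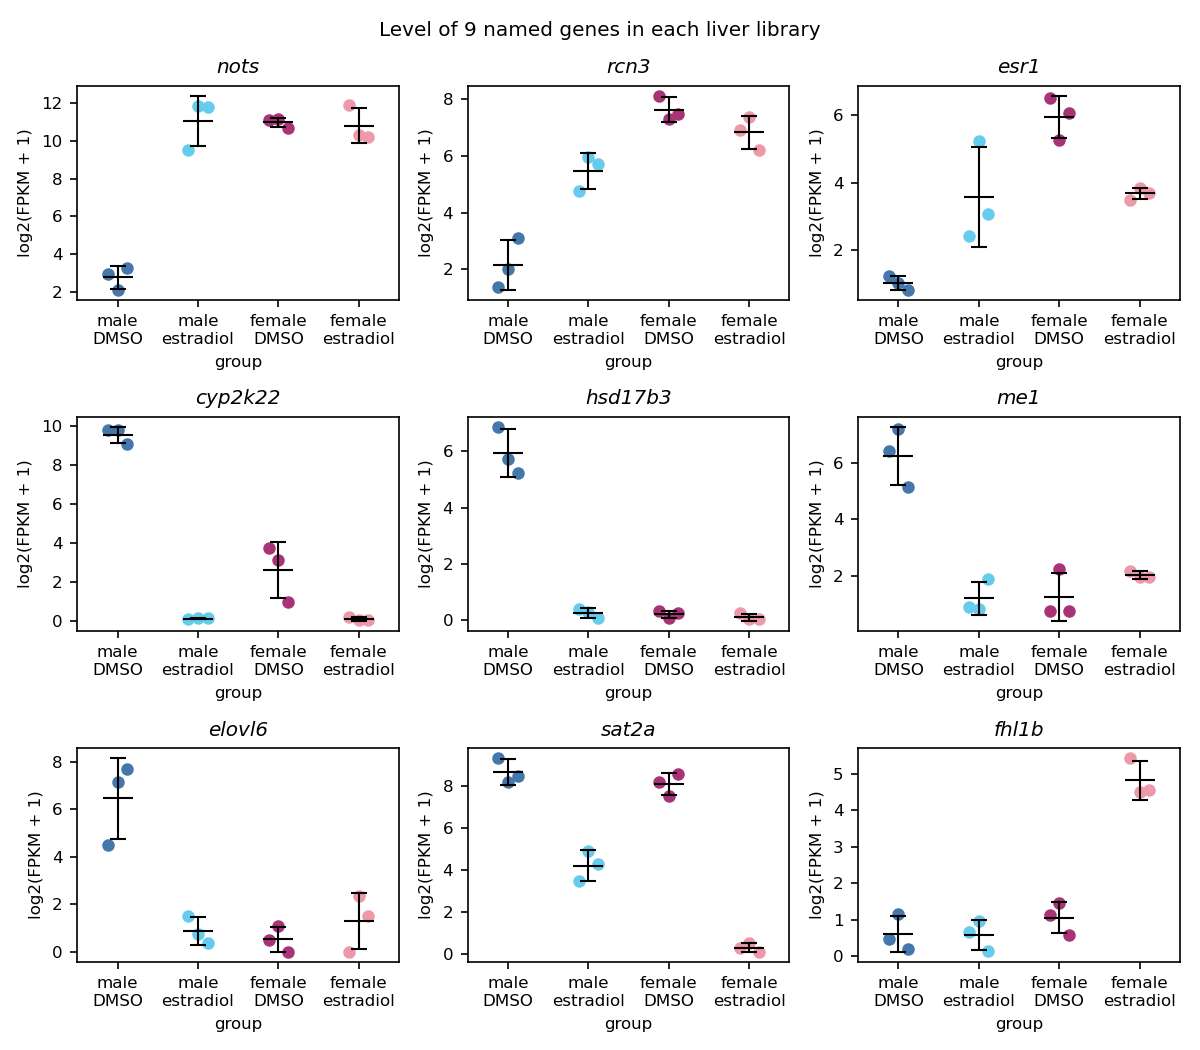
Log2(FPKM + 1) of 9 named genes (vertical axes, each panel on its own scale) in the 12 libraries by group, 1 point per library, with the mean and SD of each 3 libraries as bars. nots and hsd17b3 moved in opposite directions in estradiol males, and esr1 had a mean of 63.6 FPKM in female DMSO against 1.07 in male DMSO.

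Among the gene lists in males, cholesterol synthesis tested upward at the preset correlation. Of its 27 genes 4 rose and 0 fell (16 rose when adjusted over the list alone), and the list's median log2 change was 2.14 (camera adjusted p = 2.20e-05; adjusted p = 0.550 with an estimated correlation). idi1, an isomerase of the pathway, rose from 14.6 ± 3.67 to 90.9 ± 26.2 FPKM (log2 change 2.54, SE 0.44, adjusted p = 0.00707). hmgcs1 and sqlea, of earlier and later steps, rose by 4.28 and 5.25, but lost their calls without male DMSO replicate 1 (adjusted p = 0.120 and 0.139), male DMSO replicate 3 (0.0723 and 0.0979) or male estradiol replicate 3 (0.0590 and 0.0618). In the list for protein folding and the unfolded protein response, 3 of 42 genes rose and 1 fell (15 and 1 adjusted over the list alone), with a median of 1.18 (camera adjusted p = 1.26e-04; adjusted p = 0.563 with an estimated correlation). herpud1, of the degradation of misfolded proteins, rose from 11.95 ± 1.32 to 98.1 ± 43.8 FPKM (log2 change 2.85, adjusted p = 0.00327), and pdia2, a disulfide isomerase known from the pancreas, fell by 2.22. This list's call ended without male estradiol replicate 2 (median 0.54, camera adjusted p = 0.154). PI3K/AKT/mTOR components had 1 rise, of sesn2, and 0 falls among 41 genes (0 and 0 adjusted over the list alone), with a median of -0.24 (camera adjusted p = 0.0570). sesn2 lost its call without male DMSO replicate 1, 2 or 3 (adjusted p = 0.139, 0.158 and 0.123), male estradiol replicate 1 (0.146), female DMSO replicate 1, 2 or 3 (0.0609, 0.0689 and 0.0592) or female estradiol replicate 3 (0.0603).

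Lists of liver metabolism tested downward in males at the preset correlation. Fatty acid oxidation had 9 falls and 0 rises among 36 genes (22 falls adjusted over the list alone), with a median log2 change of -1.26 (camera adjusted p = 7.10e-14; adjusted p = 0.374 with an estimated correlation; fry adjusted p = 0.0179). etfb, an electron carrier of the pathway, fell from 135 ± 8.46 to 33.8 ± 13.01 FPKM (log2 change -2.05, adjusted p = 0.0116), a call lost without male DMSO replicate 1 (adjusted p = 0.0720) or 2 (0.0610). Xenobiotic and steroid metabolism had 12 falls, cyp2k22 and hsd17b3 among them, and 1 rise, of cyp2k6, among 62 genes (21 and 4 adjusted over the list alone; median -1.16, camera adjusted p = 4.95e-10). Glycolysis and gluconeogenesis had 6 falls and 0 rises among 36 genes (median -1.21, camera adjusted p = 3.96e-07), with fbp1b, of glucose production, down from 1781 ± 402 to 179 ± 70.7 FPKM (log2 change -3.37, adjusted p = 0.00327). Bile acid genes had 4 falls among 13 (median -1.003, camera adjusted p = 1.42e-04), with cyp8b2 down by 2.09 on the log2 scale as its values fell from 4.78 ± 0.562 to 0.356 ± 0.0714 FPKM. The lists of xenobiotics, glycolysis and bile acids had an adjusted p of 0.374 with an estimated correlation. Oxidative phosphorylation had 0 rises and 0 falls among 81 genes by limma, also when adjusted over the list alone, with a median of -0.91 (camera adjusted p = 1.32e-13; adjusted p = 0.550 with an estimated correlation).

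Cell cycle genes in males had a median log2 change of 1.95, with 1 rise among 61 genes (27 adjusted over the list alone; camera adjusted p = 7.53e-11; adjusted p = 0.550 with an estimated correlation). The rise was of kif11, a motor protein of the mitotic spindle, from 0.336 ± 0.0825 to 15.3 ± 8.35 FPKM (log2 change 3.49, adjusted p = 0.00236). The list moved with the ovary list, which had a median of 4.83 with 0 rises among 26 genes by limma (18 adjusted over the list alone). Camera's adjusted p for the ovary list was 3.96e-07 (adjusted p = 0.550 with an estimated correlation). The cell cycle median was -0.02 without the 4 estradiol libraries rich in oocyte transcripts, over the 36 genes left by the filter and with 1 male estradiol library. Coagulation genes (1 rise and 1 fall among 22, median -1.20, camera adjusted p = 6.22e-04) and complement genes (0 rises and 1 fall among 35, median -0.63, camera adjusted p = 1.98e-04) moved with it too. Both had an adjusted p of 0.563 with an estimated correlation. Without those 4 libraries their medians were 0.98 and 0.91, and both calls ended without male estradiol replicate 1 (medians -0.40 and 0.06, camera adjusted p = 0.137 and 0.0864). Exocrine pancreas genes had 19 falls and 0 rises among 23 (median -4.39, camera adjusted p = 3.45e-18; adjusted p = 0.374 with an estimated correlation). try, which encodes trypsin, fell from 1309 ± 180 to 53.9 ± 50.6 FPKM (log2 change -4.97, adjusted p = 0.00259).

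Ribosomal proteins in males had 0 rises and 0 falls among 77 genes (0 and 0 adjusted over the list alone), with a median of -0.41 (camera adjusted p = 1.00e-03; adjusted p = 0.752 with an estimated correlation). That median became 0.10 after quantile normalization and 0.20 without male estradiol replicate 1. Ribosome biogenesis had 0 and 0 among 54 by limma, with a median of 0.58 (camera adjusted p = 0.0178; adjusted p = 0.752 with an estimated correlation). This call ended without male estradiol replicate 1 (median 0.16, adjusted p = 0.474), with the ovary covariate (-0.02, 0.807), with array weights (0.21, 0.413) and without the 4 estradiol libraries rich in oocyte transcripts (0.25, 0.312). Apolipoproteins and plasma proteins had 3 rises, all of genes listed at 0 in male DMSO, and 6 falls among 35 (median -1.29, mean -0.17, camera adjusted p = 6.55e-05; adjusted p = 0.550 with an estimated correlation). This call ended with quantile normalization (median -0.78, adjusted p = 0.0820), with the ovary list level as a covariate (-0.51, 0.686) and without the 4 estradiol libraries rich in oocyte transcripts (-0.39, 0.0540). The list of estrogen receptors also holds other nuclear receptors: its 7 genes tested were esr1, esr2a, esr2b, esrra, ar, pgr and nr0b2a. It had 1 rise, of esr1, with a median of -0.89 (camera adjusted p = 0.390). The genes of the other estrogen receptors, esr2a and esr2b, had log2 changes of 0.59 and -1.36 (adjusted p = 0.409 and 0.192), the androgen receptor gene ar -1.37 (adjusted p = 0.211) and the progesterone receptor gene pgr -0.89 (adjusted p = 0.267). The list of other estrogen-responsive liver genes had 2 rises and 1 fall among 16 (6 and 2 adjusted over the list alone; median 0.66, camera adjusted p = 0.460). Fatty acid and triglyceride synthesis had 6 falls and 1 rise, of the citrate carrier gene slc25a1a, among 31 (median -0.50, camera adjusted p = 0.0274; adjusted p = 0.461 with an estimated correlation). This call too ended without male estradiol replicate 1 (median -0.30, adjusted p = 0.0868) or 2 (median -0.54, adjusted p = 0.0626). It ended as well with the ovary covariate (median -0.04, adjusted p = 0.269), a pseudocount of 0.1 (0.0530), a filter of 5 FPKM (0.133), quantile normalization (0.194), median-of-ratios scaling (0.0669) and array weights (0.143).

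**Figure D3:**
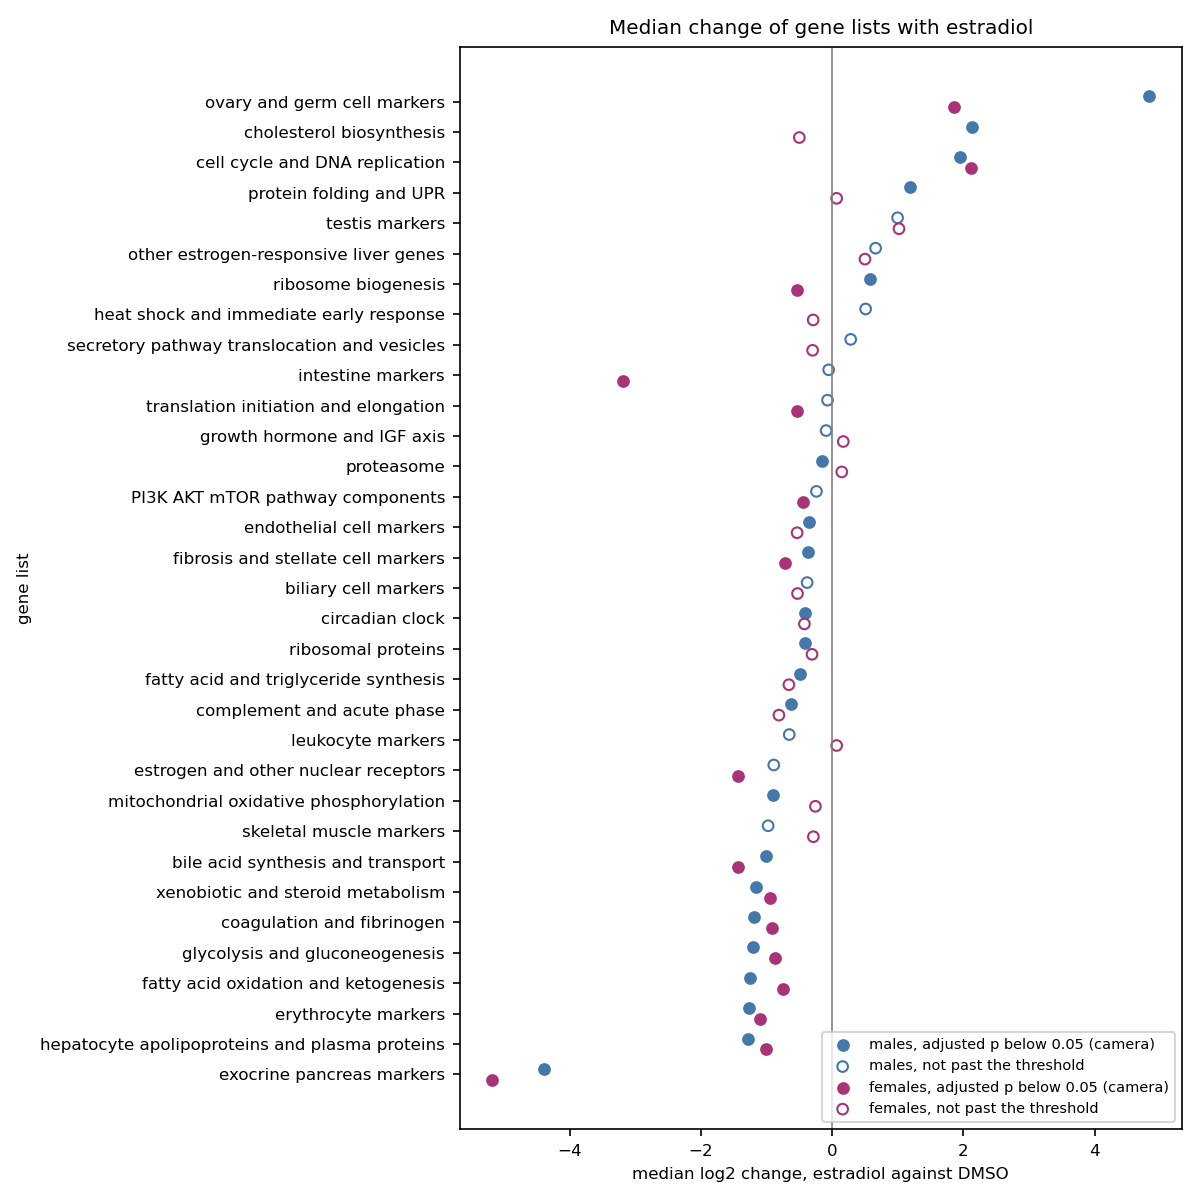
Median log2 change of gene lists with estradiol (horizontal axis), 1 point per list for males and 1 for females, filled where camera's adjusted p at the preset correlation was under 0.05. Cholesterol synthesis stood at 2.14 in estradiol males and -0.50 in estradiol females, and fatty acid oxidation at -1.26 and -0.76.

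In females, estradiol lowered sat2a, g0s2, abcg5, abcg8 and apoa1a and raised a smaller set that includes the cytokine signalling inhibitor cish. Lower too were 18 of 23 genes of the exocrine pancreas, where a difference in pancreas tissue between the samples cannot be told apart from estradiol. cish rose from 1.17 ± 0.757 to 43.6 ± 11.1 FPKM (mean ± SD, n = 3; log2 change 4.39, SE 0.55, adjusted p = 0.00360). fhl1b, a LIM domain protein gene, rose by 3.77 (SE 0.41, adjusted p = 0.00148). slc25a33, a mitochondrial pyrimidine nucleotide carrier gene, rose from 12.4 ± 7.51 to 96.6 ± 38.8 FPKM (log2 change 2.92, SE 0.48, adjusted p = 0.0106). sat2a, of the polyamine acetyltransferase family, fell from 282 ± 98.9 to 0.228 ± 0.172 FPKM (log2 change -7.80, SE 0.46, adjusted p = 4.96e-06). g0s2 fell from 736 ± 373 to 11.1 ± 6.39 FPKM (log2 change -5.90, SE 0.66, adjusted p = 0.00168). abcg5 and abcg8, which encode both parts of the sterol exporter of the bile canaliculus, fell from 17.0 ± 5.42 to 1.04 ± 0.697 FPKM and from 23.3 ± 8.79 to 1.16 ± 0.635 FPKM (log2 change -3.17 and -3.48, adjusted p = 0.00598 and 0.00564). apoa1a fell from 5229 ± 1972 to 585 ± 260 FPKM (log2 change -3.17, SE 0.47, adjusted p = 0.00599).

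Of 9190 genes in females, 251 passed the threshold by limma, 45 up and 206 down, and 1743 had an unadjusted p under 0.05. Of all genes tested 28.8% had no overlap between the groups, where chance gives 10%. The split was 74 up and 150 down after quantile normalization (median of all genes 0.01 in place of -0.08), 55 and 139 after median-of-ratios scaling (median 0.02) and 23 and 67 after rescaling (median 0.19). The count was 39 and 84 without female DMSO replicates 1 and 2 and 155, 93 and 134 without female estradiol replicates 1, 2 and 3. It was 133, 133 and 131 without male DMSO replicates 1, 2 and 3, and 492 and 711 without male estradiol replicates 1 and 2. It was 420 without the 4 estradiol libraries rich in oocyte transcripts. Without the 2 female DMSO libraries rich in intestine transcripts, which leaves 1 library whose spread is taken from the other groups, it was 13, and 44 of the 51 named calls ended, while sat2a, g0s2 and fhl1b passed in every alternative. Of the genes above, cish, slc25a33, abcg5, abcg8 and apoa1a also kept their calls without any single library.

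In females the list of xenobiotic metabolism tested downward at the preset correlation, with 8 falls and 0 rises among 62 genes (17 and 1 adjusted over the list alone; median -0.94, camera adjusted p = 1.49e-05; adjusted p = 0.638 with an estimated correlation). The sulfotransferase gene sult1st3 in this list fell from 51.8 ± 14.7 to 4.64 ± 2.57 FPKM (log2 change -3.31, SE 0.51, adjusted p = 0.00738). Fatty acid oxidation had 1 fall among 36 genes (4 adjusted over the list alone; median -0.76, camera adjusted p = 3.99e-04). Glycolysis and gluconeogenesis had 2 falls among 36 (median -0.87, camera adjusted p = 5.31e-04) and bile acid genes 2 among 13 (median -1.43, camera adjusted p = 0.0140). Each of these had an adjusted p of 0.638 with an estimated correlation. The median of fatty acid oxidation was -0.25 without the 4 libraries rich in oocyte transcripts (camera adjusted p = 0.850), and the bile acid call ended without female estradiol replicate 1 (median -0.92, adjusted p = 0.130). The bile acid call ended also without those 4 libraries (median -0.88, adjusted p = 0.393), with the ovary covariate (0.0547), with a filter of 5 FPKM (0.0527) and with array weights (0.0676). Cholesterol synthesis had 0 rises and 0 falls among 27 genes by limma, also when adjusted over the list alone (median -0.50, camera adjusted p = 0.270), and protein folding had 0 rises and 1 fall among 42 (median 0.07, camera adjusted p = 0.252). Oxidative phosphorylation (median -0.26, camera adjusted p = 0.151) and ribosomal proteins (median -0.31, camera adjusted p = 0.264) did not pass.

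Translation factors in females had 4 falls and 0 rises among 66 genes (9 falls adjusted over the list alone; median -0.54, camera adjusted p = 5.31e-04; adjusted p = 0.638 with an estimated correlation). The falls were of eif4a2, eif4bb, eef2k and eif4ebp3. The list was matched by gene name and also holds regulators, such as the repressor eif4ebp3, so its fall is not to be read as less translation. Ribosome biogenesis had 1 fall among 54 (median -0.53, camera adjusted p = 5.23e-04; adjusted p = 0.791 with an estimated correlation). The latter call ended without female estradiol replicate 3 (median -0.29, adjusted p = 0.0772). PI3K/AKT/mTOR components had 1 fall among 41 (8 adjusted over the list alone; median -0.45, camera adjusted p = 0.0152; adjusted p = 0.638 with an estimated correlation). That call was lost without female estradiol replicate 1 (median -0.39, adjusted p = 0.0933). The fall was of eif4ebp3, a translation repressor that mTOR phosphorylates, from 1168 ± 354 to 128 ± 15.7 FPKM (log2 change -3.14, SE 0.56, adjusted p = 0.0148; 0.0785 without female DMSO replicate 1 and 0.0543 without female estradiol replicate 2). The list of estrogen receptors and other nuclear receptors had a median of -1.43 with 1 fall among 7, of esrra, which is not itself an estrogen receptor (camera adjusted p = 0.00595; adjusted p = 0.638 with an estimated correlation), a call lost without female estradiol replicate 1 (median -0.86, adjusted p = 0.114). The calls of the PI3K/AKT/mTOR and receptor lists were lost also without the 4 estradiol libraries rich in oocyte transcripts (adjusted p = 0.109 and 0.114) and with array weights (0.0669 and 0.121). esrra (log2 change -2.17, adjusted p = 0.0435) lost its call without any single library other than male estradiol replicates 1 and 2 (adjusted p = 0.0521 to 0.144). esr1 had 11.9 ± 1.53 FPKM against 63.6 ± 25.8 (log2 change -2.25, SE 0.60, adjusted p = 0.0722). Other estrogen-responsive genes had 0 rises and 0 falls among 16 by limma (3 and 4 adjusted over the list alone; median 0.50, camera adjusted p = 0.445).

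Cell cycle genes in females had 0 rises and 0 falls among 61 by limma, where 33 rose when adjusted over the list alone. Their median log2 change was 2.12 with all 61 positive (camera adjusted p = 7.35e-23; adjusted p = 0.638 with an estimated correlation). The ovary list, whose level was high in female estradiol replicates 1 and 3, had a median of 1.86 with 0 rises among 26 (camera adjusted p = 3.89e-04; adjusted p = 0.779 with an estimated correlation). The ovary call ended without female estradiol replicate 1 (median 0.42, adjusted p = 0.0531). Exocrine pancreas genes had 18 falls among 23 (23 adjusted over the list alone; median -5.18, camera adjusted p = 1.74e-22; adjusted p = 0.638 with an estimated correlation). amy2a, an amylase gene, fell from 254 ± 124 to 4.76 ± 5.74 FPKM (log2 change -5.86, SE 0.76, adjusted p = 0.00389). Intestine genes had 1 fall among 7 (5 adjusted over the list alone; median -3.19, camera adjusted p = 5.23e-04; adjusted p = 0.638 with an estimated correlation). Their median was -0.06 without female DMSO replicates 1 and 2 (camera adjusted p = 0.567). Apolipoproteins and plasma proteins had 1 rise, of tfa, and 6 falls among 35 (median -1.004, camera adjusted p = 6.36e-04; adjusted p = 0.678 with an estimated correlation). This call ended without female estradiol replicate 1 (median -0.59, adjusted p = 0.0551).

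Between the sexes under DMSO, female livers had more of esr1, nots, rcn3 and eif4ebp3, and male livers had more of cyp2k22, hsd17b3, elovl6, me1 and slc27a6. esr1 stood at 63.6 ± 25.8 FPKM in females and 1.07 ± 0.284 in males (mean ± SD, n = 3; log2 difference 4.89, SE 0.60, adjusted p = 0.00161). nots stood at 2021 ± 326 against 6.23 ± 2.70 FPKM (log2 difference 8.19, SE 0.67, adjusted p = 5.59e-05), and rcn3, a calcium-binding protein gene of the endoplasmic reticulum, at 204 ± 64.8 against 4.07 ± 3.19 FPKM (5.48, SE 0.52, adjusted p = 2.36e-04). eif4ebp3 was higher in females, with 1168 ± 354 against 64.9 ± 40.0 FPKM (log2 difference 4.38, SE 0.56, adjusted p = 0.00211). Lower in females were cyp2k22 (log2 difference -6.96, SE 0.57, adjusted p = 5.59e-05), hsd17b3 (-5.74, SE 0.39, adjusted p = 1.09e-05). So were elovl6 (-5.93, SE 0.79, adjusted p = 0.00286), me1 (-4.99, SE 0.56, adjusted p = 7.78e-04) and slc27a6, of fatty acid uptake (-5.35, SE 0.68, adjusted p = 0.00200).

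Ribosome biogenesis had positive sex differences for all 54 genes, with a median of 1.45. Of these 1, wdr43, was higher in females over all genes tested and 39 adjusted over the list alone (camera adjusted p = 2.12e-27; adjusted p = 0.509 with an estimated correlation). wdr43 lost its call without any of the 6 DMSO libraries (adjusted p = 0.155, 0.176 and 0.146 without male replicates 1 to 3, and 0.153, 0.0876 and 0.0634 without female replicates 1 to 3). Ribosomal proteins had a median of 0.96 with 0 higher and 0 lower among 77 by limma, also adjusted over the list alone (camera adjusted p = 1.42e-12; adjusted p = 0.649 with an estimated correlation). Translation factors had 1 higher, the repressor gene eif4ebp3, among 66 (3 adjusted over the list alone; median 0.68, camera adjusted p = 1.47e-08). They had an adjusted p of 0.509 with an estimated correlation. Cholesterol synthesis had a median of 0.92 with 0 of 27 past the threshold (camera adjusted p = 2.93e-04; adjusted p = 0.649 with an estimated correlation). Fatty acid oxidation had a median of -0.93 with 0 of 36 past it (4 lower adjusted over the list alone; camera adjusted p = 2.56e-09; adjusted p = 0.509 with an estimated correlation). Complement had a median of -0.94 with 0 of 35 (camera adjusted p = 3.77e-06; adjusted p = 0.649 with an estimated correlation). These 6 list calls passed in every alternative at the preset correlation. PI3K/AKT/mTOR components had 1 higher, eif4ebp3, among 41 (median -0.12, mean 0.15, camera adjusted p = 0.915). The intestine list had a median of 2.56 (0 of 7 higher, 5 adjusted over the list alone; camera adjusted p = 3.45e-05; adjusted p = 0.509 with an estimated correlation), which was -0.43 without female DMSO replicates 1 and 2.

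Between the DMSO groups 51 of 9190 genes passed the threshold by limma, 22 higher and 29 lower in females, and 1058 had an unadjusted p under 0.05. Of all genes tested 30.8% had no overlap between the groups, where chance gives 10%. The count was 18, 19 and 22 without male DMSO replicates 1, 2 and 3, 30, 31 and 115 without female DMSO replicates 1, 2 and 3, 93 and 126 without male estradiol replicates 1 and 2, and 116 without female estradiol replicate 1. It was 12 without the 2 female DMSO libraries rich in intestine transcripts and 811 in a fit of the DMSO groups alone. It was 32 without the genes listed at 0, 97 with the ovary list level as a covariate and 917 without the 4 estradiol libraries rich in oocyte transcripts. The main fit shares 1 spread per gene over the 4 groups, though the estradiol libraries varied more. The lowest Spearman correlation within a group was 0.775 and 0.790 in male and female estradiol, against 0.945 and 0.910 in male and female DMSO. The count of 51 depends on that shared spread and is not the size of the sex difference. The median of all genes went from 0.05 to -0.12 after rescaling and to -0.05 after quantile normalization. Of the genes above, esr1, nots, rcn3, eif4ebp3, cyp2k22, hsd17b3, elovl6, me1 and slc27a6 kept their calls without any single library.

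Most of the genes that differed between the sexes under DMSO moved in estradiol males in the direction of that difference. Of 41 such genes, without those listed at 0 in a whole group, 39 had a log2 change in estradiol males of the same sign as the sex difference, and 30 of them passed the threshold there in that direction. The rises shared by both comparisons were 9 genes, among them esr1, nots, rcn3, rtn1a and cyp2k6, and the shared falls were 21. In 100 simulations, chosen after the data were seen, the male DMSO libraries were shared and the estradiol effects in males were dealt out among the genes at random. Of the 41 genes of smallest p for sex there, 24.5 on average and at most 32 had the same sign in both comparisons. At most 4 of them were also among as many genes of smallest p for estradiol as passed in males. These simulations passed 459 genes for sex on average, where the data passed 41, so they are a rough guide. Under estradiol 0 of the 41 genes differed between the sexes past the threshold by limma and 8 had an unadjusted p under 0.05, and the median size of their sex difference went from 3.24 to 0.61 on the log2 scale. Because the 41 genes were picked for a large difference under DMSO, part of that shrinkage is expected of any such pick. Across the 9190 genes the log2 changes of estradiol in males and of sex under DMSO had a correlation of 0.604. Noise alone, with shared male DMSO libraries and no effect of either kind, gave 0.502 on average and at most 0.541 in 100 simulations. Unrelated effects of estradiol and sex would lower that value, so it is not what the shared libraries alone give here. Without male DMSO replicate 1, 2 or 3 the correlation was 0.583, 0.604 and 0.631. Simulations of noise with 2 such libraries gave at most 0.634, 0.629 and 0.635. Because they hold no effects, they cannot decide whether the similarity rests on having all 3. The correlation was 0.540 without male estradiol replicate 2 and 0.512 without female DMSO replicate 2, where simulations with as many libraries gave at most 0.477 and 0.475. Without the 2 female DMSO libraries rich in intestine transcripts it was 0.435, against at most 0.398. The covariance was 0.684 against 0.210 in the simulations of noise alone, a difference of 0.474. The 3 male DMSO libraries serve both comparisons and are too few to be split, so part of the excess may come from them, and genes are not independent replicates. Between estradiol males and estradiol females, which share no library, 3 rises (0.341 by independent lists) and 91 falls (5.76) were shared, and the correlation was 0.583. The shared falls include exocrine pancreas genes such as amy2a and cpa4. They also include sat2a, g0s2, abcg5, abcg8 and apoa1a, so the falls of these genes described for females were not limited to females. In males abcg5 and abcg8 had log2 changes of -2.43 and -2.34 (adjusted p = 0.0122 and 0.0229 by limma).

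**Figure D4:**
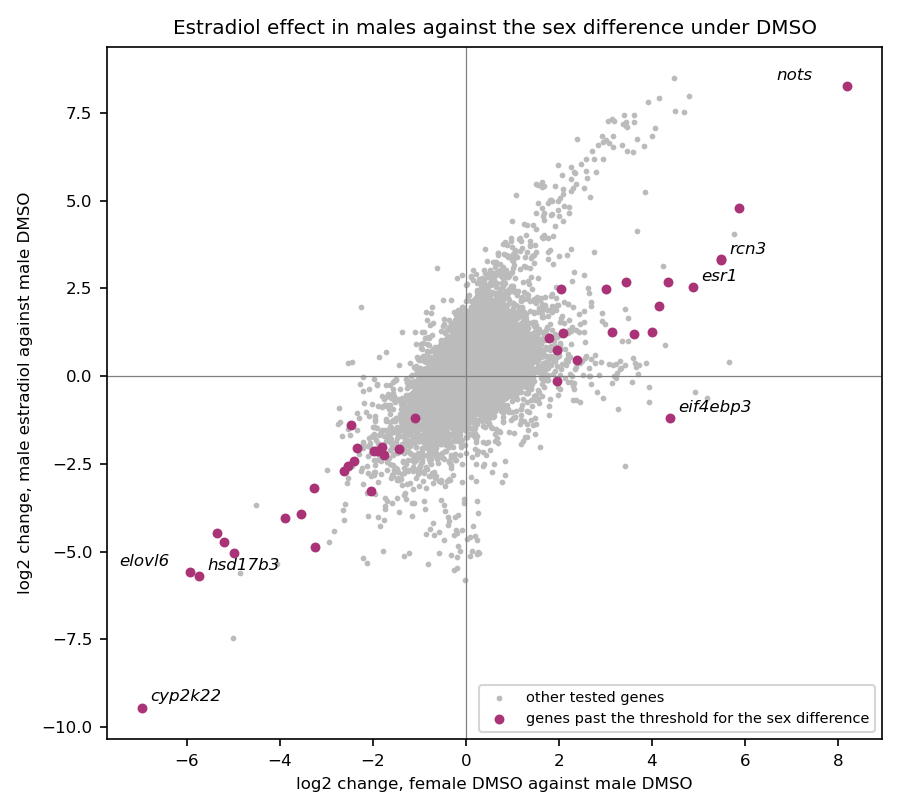
Log2 change by estradiol in males (vertical axis) against the log2 difference of females from males under DMSO (horizontal axis), 1 point per gene tested without those listed at 0 in a whole group, with the genes past the threshold for the sex difference in colour. hsd17b3 and elovl6 lie far down on the left and nots far up on the right, at 8.19 and 8.26.

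Under estradiol the sexes differed in 10 genes by limma, of which 7 were higher and 3 lower in females, and 1017 had an unadjusted p under 0.05. fhl1b, a LIM domain protein gene, stood at 28.9 ± 11.9 FPKM in females and 0.546 ± 0.426 in males (mean ± SD, n = 3; log2 difference 4.24, SE 0.41, adjusted p = 0.00208). bcat1, of branched-chain amino acid breakdown, stood at 66.9 ± 22.4 against 7.06 ± 3.84 FPKM (log2 difference 3.16, SE 0.43, adjusted p = 0.0218). sat2a was lower in females, at 0.228 ± 0.172 against 18.9 ± 9.33 FPKM (log2 difference -3.91, SE 0.46, adjusted p = 0.0101), as was cyp2x7, a cytochrome P450 gene (-3.53, SE 0.45, adjusted p = 0.0155). sult3st2, mmp23bb and lgals2a were higher in females (log2 difference 3.09, 2.87 and 2.49). esr1 did not pass, with a log2 difference of 0.10 (adjusted p = 0.956).

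Of all genes tested 12.3% had no overlap between the estradiol groups, where chance gives 10%. The count was 3 without male DMSO replicate 1, 2 or 3 or female DMSO replicate 1, 5 without male estradiol replicate 1, 30 without male estradiol replicate 2, and 1 without male estradiol replicate 3 or female estradiol replicate 2. Of the named genes fhl1b alone kept its call without each library, and in a fit of the estradiol groups alone 0 genes passed by limma and 386 had an unadjusted p under 0.05. sat2a and cyp2x7 lost theirs without male estradiol replicate 3 (adjusted p = 0.0972 and 0.110) or female estradiol replicate 2 (0.0522 and 0.0540). bcat1 lost its call without male DMSO replicates 1, 2 and 3 (0.0539, 0.0629 and 0.0531), female DMSO replicate 1 (0.0509), male estradiol replicate 3 (0.110) or female estradiol replicate 2 (0.0648). sult3st2, mmp23bb and lgals2a lost theirs without any of the 3 male DMSO libraries, male estradiol replicate 1 or 3, female DMSO replicate 1 or female estradiol replicate 2 (0.0509 to 0.155). sult3st2 lost it also without male estradiol replicate 2 (0.0559), sult3st2 and mmp23bb without female estradiol replicate 1 (0.107 and 0.0863), and sult3st2 and lgals2a without female estradiol replicate 3 (0.107 and 0.0751). Quantile normalization gave 14 higher and 3 lower (median of all genes -0.04 in place of -0.27), and rescaling 3 and 3 (median -0.58). The count was 4 with the replicate number as a block, 36 with the ovary list level as a covariate, 396 without the 4 libraries rich in oocyte transcripts and 4 without the 2 rich in intestine transcripts.

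Lists that differed between the sexes under estradiol include ribosomal proteins, with a median of 1.08 and 0 of 77 past the threshold by limma, also adjusted over the list alone (camera adjusted p = 5.93e-28). Others were oxidative phosphorylation, 0.58 with 0 of 81 (camera adjusted p = 2.48e-16), and cell cycle, 0.71 with 0 of 61 (camera adjusted p = 5.51e-11). Cholesterol synthesis had a median of -1.56 with 0 of 27 past the threshold (4 lower adjusted over the list alone; camera adjusted p = 1.12e-04), and protein folding -0.64 with 0 of 42 (camera adjusted p = 0.0369). Every list had an adjusted p of 0.985 with an estimated correlation in this comparison, and 0 of its 12 list calls, oxidative phosphorylation included, passed in every alternative. The median of ribosomal proteins was -0.22 without the 4 libraries rich in oocyte transcripts (camera adjusted p = 0.960). The cell cycle call ended without male estradiol replicate 2 (median -0.34, adjusted p = 0.902). The cholesterol call ended without male estradiol replicate 2 (-1.27, 0.0851) or female estradiol replicate 1 (-0.93, 0.327). The protein folding call ended without male estradiol replicate 2 (-0.26, 0.365) or female estradiol replicate 1 (-0.71, 0.153) or 3 (-0.44, 0.580). Other estrogen-responsive genes tested upward with a median of -0.02 and a mean of 0.25 (camera adjusted p = 0.0231). It ended without male estradiol replicate 1 (median 0.09, adjusted p = 0.341) or female estradiol replicate 3 (0.07, 0.180).

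The log2 change with estradiol differed between the sexes for 8 named genes by the interaction test. nots changed by 8.26 in males and by -0.17 in females on the log2 scale (difference -8.43, SE 0.94, adjusted p = 0.00218). hsd17b3 changed by -5.69 in males and -0.11 in females (difference 5.58, SE 0.55, adjusted p = 7.02e-04), and cyp2k22 by -9.44 and -2.52 (difference 6.92, SE 0.81, adjusted p = 0.00250). me1 changed by -5.05 and 0.77 (difference 5.82, SE 0.79, adjusted p = 0.00986). esr1 changed by 2.54 and -2.25 (difference -4.79, SE 0.85, adjusted p = 0.0442), from female and male DMSO levels of 63.6 and 1.07 FPKM. These 8 named genes also include elovl6 and slc25a48, whose effects differed by 6.35 and 6.38, and cyp2k6, by -5.28. hsd17b3, elovl6 and me1 already stood at 0.159, 0.508 and 1.70 FPKM in female DMSO, so they had little room to fall there. nots and cyp2k6, which rose in males, already stood at 2021 and 52.1 FPKM in female DMSO, against 2631 and 13.3 FPKM in male estradiol. For these genes the interaction largely repeats the sex difference under DMSO and does not show that female liver failed to respond.

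The interaction passed for 24 of 9190 genes by limma, 15 with a more positive and 9 with a more negative effect in females, 8 of the 24 being listed at 0 in a whole group, and 987 had an unadjusted p under 0.05. Quantile normalization gave 24 and 7 (median of all genes 0.05 in place of -0.28), and rescaling moved the median to -0.43. The count was 9, 6 and 10 without male DMSO replicates 1, 2 and 3, 10 without male estradiol replicate 3, 12 and 77 without female DMSO replicates 1 and 3, and 13 without female estradiol replicate 3. It was 8 without the genes listed at 0, 45 with the ovary list level as a covariate, 480 without the 4 estradiol libraries rich in oocyte transcripts and 7 without the 2 female DMSO libraries rich in intestine transcripts. nots, hsd17b3, cyp2k22 and me1 kept their calls without any single library. esr1 lost its call without male DMSO replicates 1, 2 and 3 (adjusted p = 0.169, 0.182 and 0.194), male estradiol replicate 3 (0.0930), female DMSO replicate 1 or 2 (0.159 and 0.0617) or female estradiol replicate 1, 2 or 3 (0.0803, 0.103 and 0.128). elovl6 lost its call in 9 of the 12 runs that leave out 1 library (adjusted p = 0.0554 to 0.182). These were the runs without male DMSO replicates 2 and 3, male estradiol replicates 1 to 3, female DMSO replicates 1 and 2 and female estradiol replicates 2 and 3. cyp2k6 lost its call without male DMSO replicates 1 to 3, female DMSO replicate 1 or 2 or female estradiol replicate 3 (0.0546 to 0.121), and slc25a48 without male DMSO replicate 1 or 2 (0.0595 and 0.0822).

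By lists, the effects differed for cholesterol synthesis, with a median difference of -2.61 and 0 of 27 past the threshold by limma (7 lower adjusted over the list alone; camera adjusted p = 7.23e-08). They differed also for ribosome biogenesis, -1.14 with 0 of 54 (camera adjusted p = 4.79e-08), and fatty acid oxidation, 0.62 with 0 of 36 (camera adjusted p = 1.05e-05). These 3 calls passed in every alternative at the preset correlation, and each had an adjusted p of 0.891 with an estimated correlation. Protein folding had a median difference of -0.93 (camera adjusted p = 0.00311; adjusted p = 0.891 with an estimated correlation). This call ended without male estradiol replicate 2 (adjusted p = 0.597) or female estradiol replicate 3 (0.0593). Oxidative phosphorylation had a median difference of 0.69 (camera adjusted p = 1.04e-09, and 0.891 with an estimated correlation), a call that did not pass in every alternative. PI3K/AKT/mTOR components had a median difference of -0.43 with 0 of 41 past the threshold (camera adjusted p = 0.563) and the list of estrogen receptors and other nuclear receptors -0.81 with 1, esr1, of 7 (camera adjusted p = 0.109). Glycolysis and gluconeogenesis tested upward with a median of 0.19 and a mean of -0.01 (camera adjusted p = 0.0372; adjusted p = 0.891 with an estimated correlation). This call ended without male DMSO replicate 3 (adjusted p = 0.0776), male estradiol replicate 1 (0.614), female DMSO replicate 1 (0.108) or female estradiol replicate 2 or 3 (0.138 and 0.139). It ended also with no filter (0.0785), a filter of 5 FPKM (0.0550), quantile normalization (0.309), median-of-ratios scaling (0.0719) and the ovary covariate (0.651), and without the 4 estradiol libraries rich in oocyte transcripts (0.662) or the 2 female DMSO libraries rich in intestine transcripts (0.179).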

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

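The interaction between sex and estradiol was planned before the data were examined, while the tests of explanations and the counts over other splits of the samples were chosen after the results were seen. The effect of estradiol differed between males and females by the interaction term of limma for 24 genes, and for 8 when the genes listed at 0 in a whole group were left out. The count was 9, 6 and 10 without male DMSO replicates 1, 2 and 3, 10 without male estradiol replicate 3, 12 and 77 without female DMSO replicates 1 and 3, and 13 without female estradiol replicate 3. Among the named genes the difference (effect in females minus effect in males, log2) was 6.92 for cyp2k22, 6.38 for slc25a48, 6.35 for elovl6, 5.82 for me1 and 5.58 for hsd17b3, all genes that fell in males. It was -8.43 for nots, -5.28 for cyp2k6 and -4.79 for esr1, all genes that rose in males. Female DMSO levels of hsd17b3, elovl6 and me1 were 0.159, 0.508 and 1.70 FPKM, which left little room for a fall in females. Those of nots, cyp2k6 and esr1 were already 2021, 52.1 and 63.6 FPKM, against 2631, 13.3 and 16.1 FPKM in male estradiol.

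Over 100 splits that regroup the libraries within each sex, the real one among them, 3 gave as many genes for the interaction as the real split. The highest other split gave 1078 genes against 24. It kept the estradiol and DMSO groups whole and exchanged their labels in 1 sex, so it called the effect of estradiol that males and females share. Such splits break up the effect of estradiol along with its difference between the sexes, so whether chance can be excluded stays open for the interaction. The 10 splits of 6 libraries are too few for a share under 0.05 in the pairwise comparisons. For these the real count and the highest other were 348 and 2 for estradiol in males, 251 and 0 in females, and 51 and 0 for sex under DMSO (1 of 10 splits as large in each, the real one). For sex under estradiol 2 of 10 splits gave as many genes. The real split gave 10 and the other 1383, and it set male estradiol replicates 1 and 3 and female estradiol replicate 1, which hold oocyte transcripts, against the rest. The rest included female estradiol replicate 3, which holds such transcripts too.

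Oocyte transcripts stood high in 4 estradiol libraries, 2 labelled male and 2 labelled female, with zp3b at 609, 286, 376 and 104 FPKM. A swap of labels between the male and female estradiol groups as the whole cause is argued against, because only 1 female estradiol library lacks these transcripts and an exchange with it would leave 1 library labelled male that holds them. Ovarian RNA of 1 composition carried into the liver samples would keep its genes in 1 ratio, but the log2 ratio between 2 of the 4 libraries had an SD of 0.518 to 1.22 across the 26 ovary list genes over 6 pairs. buc and zp2.5, picked after their values were seen, stood at 153 and 127 FPKM in male estradiol replicate 1 and at 65.9 and 598 in female estradiol replicate 1. Ovaries at different stages were not measured and may differ in such ratios, so carried ovarian RNA stays open. For the male libraries it would also need tissue from another fish, a wrong label from outside these groups or a change in the males' own gonads, which were not measured. Estradiol having switched on oocyte genes in liver cells, or having changed the gonads of the males, stays open: 4 of 6 estradiol libraries lay above the highest DMSO library (3.35), and the other 2 did not.

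Abundant liver genes were listed at exactly 0 in whole groups, in 4 of the 20 genes with the highest values against 11 of the 980 at ranks 21 to 1000. This excess (p = 1.38e-04, Fisher's exact test, two-sided) is what drew attention to these genes, so it does not support estimates left at 0 at the most abundant loci. Failed estimates and transcription off in the groups listed at 0 cannot be told apart with these values. Liver makes vitellogenins under estrogen, so their 0 in the female and estradiol libraries is not to be read as silencing by estradiol. Of 46 genes that reach 10000 FPKM in some library 4 had an exact 0, and 0 had a lowest value between 0 and 1 (the lowest non-zero minimum was 1.75), which is too few to say how often a gene this abundant is merely low.

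Gene lists moved with estradiol while the oocyte transcripts in the libraries, whatever their origin, the scaling of the libraries and the order in which they were made could each move them too. The covariate measures the level of the ovary list and not where it came from. With the ovary list level as a covariate the fall of fatty acid oxidation in males was -0.89 (quartiles -1.42 to -0.49) and the rise of the cell cycle list in females 1.53 (1.26 to 1.82), which argues against oocyte transcripts as the whole cause of either, and the smallest fall of fatty acid oxidation in males over 3 other scalings was -0.81 (-1.30 to -0.45), which argues against scaling. The coagulation list in males went from -1.20 (quartiles -1.49 to -0.60) to 0.28 (-0.33 to 0.55), so its call ended because the change itself was gone, consistent with what raised the oocyte transcripts as its source. For the cell cycle list in males oocyte transcripts stay open as the source, since its median was 0.63 with the covariate (0.22 to 0.94) and -0.02 without the 4 libraries (-0.47 to 0.44). The latter median covers only 36 of its 61 genes, those left by the filter, and 1 male estradiol library. Libraries made in 2 runs cannot be told apart from estradiol for fatty acid oxidation in males, since 0 DMSO libraries are numbered among the estradiol libraries.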

How the results depend on the processing

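Chosen after the data were seen were the run without the genes listed at 0, the ovary list level as a covariate, and the runs without 4 estradiol libraries rich in oocyte transcripts and without 2 female DMSO libraries rich in intestine transcripts; the other alternatives were planned. Of the named genes past the threshold, 21 of 57 in estradiol males, 4 of 51 in estradiol females, 7 of 19 between the sexes under DMSO, 0 of 7 under estradiol and 2 of 8 in the interaction kept their calls under every alternative. Without any single library 22, 15, 13, 1 and 4 kept them. None reversed in limma. Lost calls of named genes numbered 262 of 1472 runs, 332 of 1314, 80 of 490, 61 of 182 and 44 of 197. Of the list calls at the preset correlation 8 of 21, 5 of 16, 7 of 20, 0 of 12 and 3 of 17 held under every alternative. With an estimated correlation 0 lists passed in any comparison by camera (lowest adjusted p = 0.374, 0.638, 0.509, 0.985 and 0.891), and fry called 4, 1, 0, 0 and 0. The depth of the libraries is unknown and sets no limit that can be stated here.

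The counts of genes past the threshold ranged, over the runs that leave out 1 library, from 104 to 2220 for estradiol in males, 39 to 711 in females, 18 to 126 for sex under DMSO, 1 to 30 for sex under estradiol and 6 to 77 for the interaction. The similarity of the estradiol effect in males and the sex difference ranged from 0.512 to 0.636. Array weights gave 5526, 2005, 1775, 2061 and 1803 genes and a similarity of 0.554, but the weights did not converge. Fits of only the groups compared gave 220 genes in males, 811 for sex under DMSO and 0 for sex under estradiol in limma (386 at an unadjusted p under 0.05). They estimate the spread from fewer libraries and, for sex under DMSO, without the estradiol libraries, which varied more within a group. The ovary covariate gave 205 in males, 97 for sex under DMSO, 36 for sex under estradiol and 45 for the interaction. Without the 4 estradiol libraries the counts were 693, 420, 917, 396 and 480 and the similarity 0.549, with 1 library left in each estradiol group, assumed to vary like the other groups. Without the 2 female DMSO libraries, with 1 left in that group, they were 197, 13, 12, 4 and 7 and the similarity 0.435. Leaving out the genes listed at 0 gave 32 for sex under DMSO and 8 for the interaction, rescaling 90 in females and 6 for sex under estradiol, and quantile normalization 17 and the replicate block 4 for the latter, although the numbers do not pair the libraries. The similarity was 0.655 with a pseudocount of 0.1 and 0.658 with a filter of 5 FPKM. Where no reason is given the cause was not tested.

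The lists whose camera test turned to the other direction, which need not change the sign of the median, had these medians. For estradiol in males, ribosomal proteins stood at 0.10 with quantile normalization, 0.088 with array weights, 0.34 without the 4 libraries and -0.77 to 0.20 over the runs without 1 library. With the ovary covariate ribosome biogenesis stood at -0.017, coagulation at 0.28, complement at 0.25, the circadian clock at 0.32 and the ovary list at -0.17. Without the 4 libraries cell cycle, over the 36 genes left by the filter, stood at -0.024, coagulation at 0.98 and complement at 0.91. For estradiol in females the ovary list stood at -2.40 without the 4 libraries. For sex under DMSO the intestine list stood at -0.43 without the 2 female libraries and the ovary list at 0.019 with the covariate. For sex under estradiol translation factors stood at -0.40 without the 4 libraries and the proteasome at -0.24 with array weights, and without 1 library protein folding ran from -1.08 to -0.26, where its test turned, and coagulation from -1.62 to 0.016. For the interaction ribosomal proteins stood at -0.039 with quantile normalization, -0.87 with array weights, -1.16 without the 4 libraries and -0.50 to 0.44 without 1 library. Cell cycle stood at -0.32 with array weights and -0.97 to 0.97 without 1 library, and complement at -0.49 with the covariate, -1.45 without the 4 libraries and -0.53 to 0.92 without 1 library. The cause of these turns was not tested beyond the runs named.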

Other observations

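The lists of this part were fixed before the data were examined, and the runs without 4 estradiol libraries or with the ovary covariate were chosen after the results were seen. Calls with estradiol in lists of protein export, growth signalling and stress can be set against 348 of all 9190 genes in males and 251 in females. The growth hormone axis in males and heat shock genes in females had a larger share of calls than all genes, though neither list passed by camera. In males the secretory pathway had 1 rise among 52 genes (median log2 change 0.28, camera adjusted p = 0.317) and the growth hormone axis 1 rise and 3 falls among 19 (median -0.09, camera adjusted p = 0.0570). Heat shock and immediate early genes had 0 rises and 0 falls among 26 by limma, also when adjusted over the list alone (median 0.51, camera adjusted p = 0.375). The proteasome had 1 fall among 50 (median -0.15, camera adjusted p = 0.0315; adjusted p = 0.752 with an estimated correlation). The circadian clock had 1 fall among 33 (median -0.41, camera adjusted p = 0.0162; adjusted p = 0.630 with an estimated correlation). Both calls ended without male estradiol replicate 1 (adjusted p = 0.0570 and 0.0739) or 3 (0.0527 and 0.0641), and that of the proteasome without male DMSO replicate 3 (0.0723). Without the 4 estradiol libraries rich in oocyte transcripts they ended too (0.163 and 0.935). The proteasome call ended also with a filter of 5 FPKM (0.191), quantile normalization (0.30002) and rescaling (0.307), and the clock call with the ovary covariate (0.269). Translation factors stood at a median of -0.07 with 0 of 66 past the threshold (camera adjusted p = 0.209). In females the following 7 lists did not pass. The secretory pathway had 0 rises and 0 falls among 52 by limma, also adjusted over the list alone (median -0.30, camera adjusted p = 0.140), and the growth hormone axis 1 rise among 19 (0.17, 0.178). Heat shock and immediate early genes had 3 falls among 26 (-0.29, 0.345), the proteasome 2 falls among 50 (0.15, 0.380) and the circadian clock 1 fall among 33 (-0.42, 0.0667). Complement had 1 rise and 2 falls among 35 (-0.81, 0.174) and fatty acid synthesis 2 falls among 31 (-0.66, 0.171). Coagulation passed (-0.92, camera adjusted p = 0.0137; adjusted p = 0.804 with an estimated correlation) with 0 falls by limma and 3 adjusted over the list alone. This call ended without female DMSO replicate 3 (adjusted p = 0.0541) or female estradiol replicate 1 (0.247), and with a filter of 5 FPKM (0.0532), quantile normalization (0.104) and the ovary covariate (0.367).

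Markers of other liver and blood cell types tested lower or did not pass in estradiol livers. Red blood cell genes had 1 fall among 9 in males (median -1.27, camera adjusted p = 1.89e-04; adjusted p = 0.461 with an estimated correlation). They had 1 among 9 in females (median -1.10, camera adjusted p = 0.00469; adjusted p = 0.638 with an estimated correlation). The female call ended without female estradiol replicate 3 (median -0.53, adjusted p = 0.158) or without the 4 estradiol libraries rich in oocyte transcripts (-0.97, 0.552). Stellate cell and fibrosis markers had 1 fall among 14 in males (median -0.37, camera adjusted p = 0.00642; adjusted p = 0.550 with an estimated correlation) and 0 by limma in females (median -0.72, camera adjusted p = 0.00902; adjusted p = 0.638 with an estimated correlation). Both calls ended without a single library, male estradiol replicate 1 (median -0.25, adjusted p = 0.0603) and female estradiol replicate 1 (-0.52, 0.122). Both ended also without the 4 estradiol libraries rich in oocyte transcripts (0.113 and 0.156) and with array weights (0.0987 and 0.147). The male call ended with the ovary covariate (0.174), and the female call with a filter of 5 FPKM (0.0834) and without the 2 female DMSO libraries rich in intestine transcripts (0.0631). Endothelial markers stood at -0.36 in males (camera adjusted p = 0.00837; adjusted p = 0.550 with an estimated correlation) and -0.53 in females (camera adjusted p = 0.0524). The male call ended with the ovary covariate (median -0.10, adjusted p = 0.647) and without those 4 libraries (0.13, 0.665). Biliary markers stood at -0.38 and -0.53 (0.209 and 0.135), leukocyte markers at -0.65 and 0.07 (0.0564 and 0.379), muscle markers at -0.98 and -0.29 (0.0996 and 0.527), and testis markers at 0.997 and 1.02 (0.531 and 0.232). Intestine markers in males had a median of -0.05 and a mean of 0.01 (camera adjusted p = 0.608). Leukocyte markers tested higher in females than in males under estradiol (median 0.80, camera adjusted p = 1.90e-05; adjusted p = 0.985 with an estimated correlation), with 0 of 15 past the threshold by limma (1 adjusted over the list alone). The median was 0.00 without the 4 libraries rich in oocyte transcripts (camera adjusted p = 0.266).

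Ribosomal protein genes made up 20.3 to 56.2% of the FPKM sum, with the lowest and highest shares in male and female estradiol replicate 1. The first principal component held 50.03% of the variance of the tested genes and the second 10.8%. Male and female estradiol replicates 1 and 3, the 4 libraries with oocyte transcripts, stood at 112, 56.4, 112 and 41.2 on the first component, and the other 8 libraries at -70.4 to -4.73.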
